A study of Escherichia coli with 6 samples.

How the data were processed

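Per the labels, 3 independent cultures of each strain, E. coli K-12 MG1655 and O157 Sakai, were processed on different days. Each was grown in EZ Rich Defined Medium at 37 °C to an OD600 of 0.4, divided, and shaken for 10 min with menadione at 0.5 mg/ml or with water. Per the labels, RNA was stabilised with RNAprotect, extracted with RNeasy and treated with DNase, 20 µg was used for post-labelling cDNA with CyScribe, and treated RNA carried Cy5 and untreated RNA Cy3. There were 6 arrays and no dye exchange, so a dye effect peculiar to a gene stays in a strain's mean ratio and leaves the strain difference only if equal in both strains. The scanner software, background correction, normalization and centring were not given in the sources used here.

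The authors deposited 1 log ratio per spot and array. In 5 columns the values deposited were natural log ratios, and in the column of O157 replicate 1 they were log2 ratios. This was settled from the values, which peak at the logs of 2, 1.5 and 3 (for 186 and 3 spots of K-12 replicate 1 at the natural log and log2 of 2, but 4 and 177 of O157 replicate 1) and end at 11.513 or 16.61, the natural log and log2 of 100000. The direction, treated over untreated, was taken as likely because the labels call the untreated RNA the reference. All columns were converted to log2. A ratio of 100000, the ceiling, was taken to mark a denominator without signal and was set to missing, and blanks were left missing. Ratios of whole numbers up to 10 mark dim spots. A gene with at least 50% of its spot values in a strain missing or such ratios was counted as near the signal floor (406 of the genes tested in K-12 and 340 in O157).

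The probe table named 1 gene for 6412 spots, several for 48 and none for 7940, which gave 3206 genes, each the mean of 2 spots. The annotation of 2007 was matched by Entrez gene identifier to assembly ASM584v2 for 6394 spots, 18 spots of 9 genes had no match, and 0 symbols changed. The annotation named K-12 genes only and did not tell which genes O157 has or lacks. The gene marA was not among the named spots and was not analysed here.

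Genes with a value on each of the 3 arrays of a strain were tested in that strain, and those with values on all 6 in the difference. A means model with 1 coefficient per strain was fitted to the 6 arrays with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 4 residual degrees of freedom), and K-12, O157 and O157 minus K-12 were tested against 0. P values were adjusted by Benjamini and Hochberg over the genes of each comparison, with calls at 0.05. The prior carried 7.72, 7.56 and 7.80 degrees of freedom. Overlap of calls was tested with Fisher's exact test.

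Of 29 gene lists written from general knowledge, 26 had measured members. They were tested in 3 comparisons, 78 tests, with camera (preset correlation 0.01, genes complete on 6 arrays), with camera on an estimated correlation, and with fry, adjusted over the lists of a comparison. Member counts were also made with p values adjusted over the list alone. The genes named in the report follow a rule fixed beforehand. It took the 10 highest and 10 lowest called ratios of a comparison and up to 4 called members of each list with the largest change. Where fewer than 2 members of a list were called, the 2 with the largest change were taken, called or not. A further 9 genes were named always, of which soxS, sodA, fumC, zwf, katG, ahpC, nemA and recA were measured. Genes outside this rule are marked as named after their values were seen.

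The median SD between arrays was 0.40 in K-12 and 0.41 in O157, and spot intensities were not used here, so signal over background was not computed. The procedure was tested on simulated data with the spread of these arrays, 100 genes changed at each size. Of 2-fold changes 51% were recovered in K-12, 51% in O157 and 16% in the difference, and of 4-fold changes 92%, 91% and 74%. Unchanged genes called numbered 6, 5 and 3, and 0 of 78 tests of random lists passed. The genes were simulated as independent, while the correlation estimated within the real lists was 0.17 to 0.74. The random lists therefore do not test the calls that camera made with its preset correlation.

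The alternatives were centred arrays, arrays scaled to one median absolute deviation, quantile normalization, each spot alone, values on at least 2 arrays per strain, values on all 6 arrays, all spots with unnamed ones, a replicate block, array quality weights (statmod 1.5.0), robust eBayes, an adjusted p of 0.01, a 2-fold minimum, each array left out in turn, 1 strain alone and an unmoderated statistic. Added later were all columns read as natural logs, genes near the floor left out, and scaled arrays and quantile normalization for the list tests. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.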

Results

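The series measured how 2 strains of Escherichia coli respond to menadione, the laboratory strain K-12 MG1655 and the enterohaemorrhagic strain O157 Sakai. Menadione is a quinone that cycles between oxidised and reduced forms in the cell and passes electrons to oxygen, which yields superoxide. Per the labels, each culture in a rich defined medium at 37 °C was divided at an optical density of 0.4, and the parts were shaken for 10 min with menadione at 0.5 mg/ml or with water. Each of 6 slides carried cDNA of a treated part in Cy5 and of the untreated part of the same culture in Cy3, with 3 independent cultures and 3 slides per strain. Of 14400 spots, 6412 were annotated to a single gene and gave 3206 genes with 2 spots each. A ratio was present for 12652 to 13410 spots per array, and the paired spots of a gene correlated across genes at r = 0.904 to 0.969 within an array. The SD of the log2 ratios across named genes was 1.04, 0.83 and 0.85 on K-12 arrays 1 to 3 and 1.5, 1.12 and 1.24 on O157 arrays 1 to 3. Across genes, which are not independent replicates, arrays correlated at r = 0.662 to 0.758 within K-12, 0.843 to 0.904 within O157 and 0.502 to 0.685 between strains. K-12 array 3 was closest to K-12 array 2 (r = 0.756). It was closer to O157 array 2 (r = 0.685, Spearman's rho = 0.592) than to K-12 array 1 (0.662 and 0.487). By rho, each O157 array (0.530 to 0.592) was closer to it than K-12 array 1. Its array quality weight was the lowest, 0.41. All ratios are given as log2 of treated over untreated, a direction that is likely because the labels call the untreated RNA the reference, but that is not stated with the values. Only 3 arrays per strain were made, and their number limits the precision of every value.

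In K-12, menadione raised transcripts of the superoxide and peroxide defences within 10 min. The transcript of soxS (b4062), the activator of the superoxide response, rose 55.3-fold, a log2 ratio of 5.79 ± 0.46 (SD, n = 3, limma adjusted p = 8.93e-08). The transcript of sodA (b3908), the manganese superoxide dismutase, rose to 5.92 ± 1.98, with more spread between arrays, and katG (b3942), the catalase-peroxidase, rose to 5.42 ± 0.40. The azoreductase gene azoR (b1412), whose product reduces quinones, rose to 5.50 ± 0.48, and the iron-sulphur scaffold gene sufA to 5.30 ± 1.52. The largest fall among called genes was that of ompF (b0929), a major outer membrane porin, to −3.68 ± 0.35 (adjusted p = 1.04e-06). The other genes among the 10 with the highest ratios were ybiJ (5.97 ± 0.91), sufC (5.07 ± 1.45), the fumarase gene fumC (5.02 ± 0.43), the ferritin-like dps (5.00 ± 0.36) and the nickel and cobalt exporter gene rcnA (4.82 ± 0.83). After ompF, the lowest ratios were those of pdeL (−2.57 ± 1.39), yobF (−2.52 ± 0.10), the acetate and succinate permease gene satP (−2.43 ± 0.26), grcA (−2.41 ± 0.69), yjbM (−2.38 ± 0.76), rhaM (−2.25 ± 0.64), the phenylalanine permease gene pheP (−2.23 ± 1.24), cspC (−2.21 ± 0.39) and yjdM (−2.16 ± 0.20). Of the spot values of yjbM on K-12 arrays, 66.7% were missing or were ratios of small whole numbers, the mark of a dim spot. The calls of yjbM and pheP were lost when each spot had to pass alone. The ratios of recA, the recombinase that starts the SOS response (0.41 ± 0.21, adjusted p = 0.258), and of the N-ethylmaleimide reductase gene nemA (0.49 ± 0.03, adjusted p = 0.154) did not pass.

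In all, 512 of the 3180 genes tested in K-12 changed at an adjusted p of 0.05 in limma's test. Of these, 330 rose and 182 fell, and 371 differed at least 2-fold. The count was 254 without K-12 replicate 1 and 268 without K-12 replicate 2, and without K-12 replicate 3 it was 482 with 79.5% of calls higher in place of 64.5%. It was 1056 after quantile normalization, 928 with array quality weights, 273 at an adjusted p of 0.01, and 0 with an unmoderated statistic on the 3 arrays. The main fit, which gave the 512 calls, had 907 genes at an unadjusted p under 0.05 in limma's test.

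**Figure D1:**
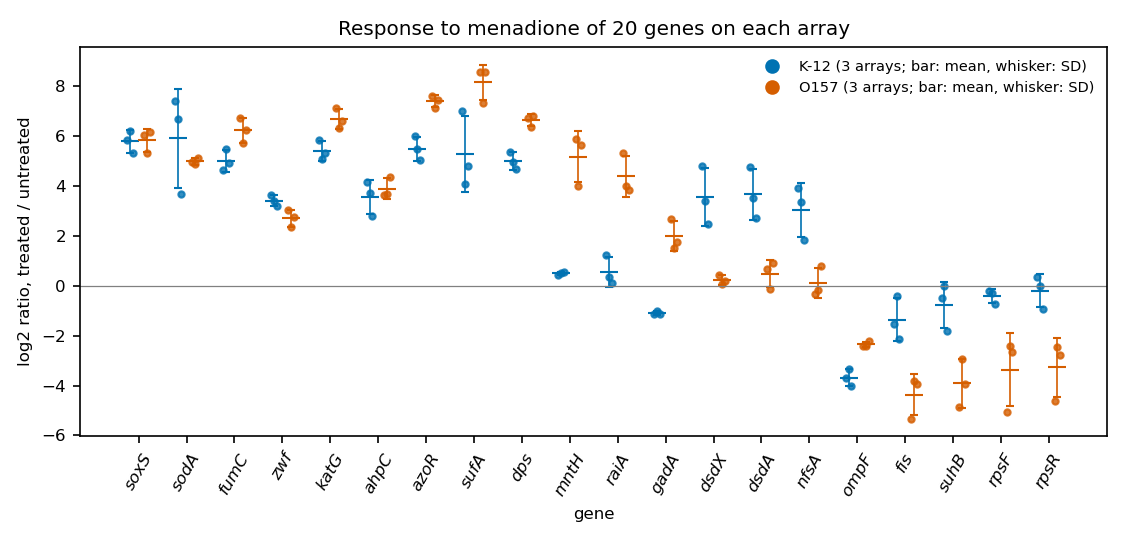
Log2 ratio of treated over untreated RNA (vertical axis) of 20 genes (horizontal axis), 1 point per array, with the mean as a bar and the SD as a whisker for 3 K-12 arrays (blue) and 3 O157 arrays (orange). The means of soxS are 5.79 and 5.84, those of mntH 0.51 and 5.18, and those of dsdX 3.56 and 0.24.

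The oxidative stress lists fixed before the data were examined moved up together in K-12. Some lists share members, so their calls are not independent of each other. The suf genes are in the OxyR and iron-sulphur lists, and trxC is in the OxyR and thioredoxin lists. Likewise fumC and acnA are in the SoxRS and tricarboxylic acid cycle lists, and zwf in the SoxRS and pentose phosphate lists. The genes acrA, acrB and tolC are in the SoxRS and drug efflux lists. Both talA and tktB are in the pentose phosphate and general stress (RpoS) lists. As written, the lists also share grxA (OxyR and thioredoxin) and fhuF (OxyR and iron acquisition). They share sdhA, sdhB, sdhC and sdhD as well (tricarboxylic acid cycle and aerobic respiratory chain). In the SoxRS regulon, genes under the superoxide sensor, 25 of 27 measured members rose, 25 when adjusted over the list alone, and the median log2 ratio was 3.04 (camera adjusted p = 7.58e-30). The call of this list was lost with a correlation estimated from the arrays (adjusted p = 0.238 with an estimated correlation). Beside soxS and sodA, the members with the highest ratios were fumC and the flavodoxin reductase gene fpr (4.77 ± 0.80), and zwf, the first enzyme of the pentose phosphate pathway, rose to 3.42 ± 0.22. In the OxyR regulon, the peroxide response, 15 of 18 members rose and 0 fell, with 15 rising and 1 falling when adjusted over the list alone (median 2.96, camera adjusted p = 1.62e-15, adjusted p = 0.304 with an estimated correlation). Its members include katG, dps and the alkyl hydroperoxide reductase gene ahpC (3.55 ± 0.69). All 14 members of the iron-sulphur cluster assembly list rose, over all genes and adjusted over the list alone, with a median of 2.29 (camera adjusted p = 9.73e-16, adjusted p = 0.201 with an estimated correlation). The suf genes had the highest ratios among them (sufD 4.76 ± 1.47, sufE 4.03 ± 0.84). Of 33 iron acquisition genes, 20 rose, 27 when adjusted over the list alone, led by the enterobactin synthesis gene entC (3.33 ± 1.14) and the siderophore receptor gene cirA (3.28 ± 1.26). The median of this list was 1.46 (camera adjusted p = 2.06e-11, adjusted p = 0.544 with an estimated correlation). Without K-12 replicate 1 its median was 0.78 and 11 members rose. Of 16 genes for quinone and electrophile detoxification, 9 rose, 13 when adjusted over the list alone (median 1.32, camera adjusted p = 9.95e-10, adjusted p = 0.544 with an estimated correlation). Beside azoR, the pirin-like quercetinase gene yhhW stood at 4.62 ± 0.20 and the glutathione-dependent formaldehyde dehydrogenase gene frmA at 3.76 ± 0.83. Of 17 genes for ribonucleotide reduction and the thioredoxin and glutaredoxin systems, 7 rose, with 9 rising and 1 falling when adjusted over the list alone (median 0.74, camera adjusted p = 0.000467, adjusted p = 0.544 with an estimated correlation). The manganese-dependent reductase genes nrdI (4.38 ± 0.93) and nrdE (4.25 ± 1.52) led them.

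Heat shock genes rose as a group in K-12, with 16 of 17 members called, 17 when adjusted over the list alone, such as the chaperone genes htpG (1.87 ± 0.14) and groS (1.65 ± 0.69). The median of this list was 1.22 (camera adjusted p = 5.94e-10, adjusted p = 0.238 with an estimated correlation). Only 9 heat shock members rose without K-12 replicate 1, and 9 without K-12 replicate 2. In the tricarboxylic acid cycle, 8 of 18 genes rose, 9 when adjusted over the list alone (median 0.65, camera adjusted p = 0.0101, adjusted p = 0.609 with an estimated correlation). Here fumC and the aconitase gene acnA (2.75 ± 0.32) had the highest ratios, and 3 members rose without K-12 replicate 1 and 2 without K-12 replicate 2. In the pentose phosphate pathway 4 of 10 rose, 4 when adjusted over the list alone (median 0.53, camera adjusted p = 0.0135, adjusted p = 0.544 with an estimated correlation), led by zwf and edd (1.77 ± 0.37). Without K-12 replicate 1, and likewise without K-12 replicate 2, 2 of these rose. Of 9 acid resistance genes 4 fell, 5 when adjusted over the list alone, with a list median of −0.89 (camera adjusted p = 0.000127, adjusted p = 0.544 with an estimated correlation). Among these, the regulator genes gadE and gadX stood at −1.63 ± 0.26 and −1.33 ± 0.06. Biosynthesis genes fell in small numbers: 4 of 14 in purine synthesis (6 when adjusted over the list alone, median −0.73, camera adjusted p = 9.81e-06, adjusted p = 0.544 with an estimated correlation). The transformylase gene purT had the lowest ratio of these (−1.50 ± 0.48), and only 1 purine gene fell without K-12 replicate 1 or without K-12 replicate 3. Among branched-chain amino acid genes 4 of 9 fell, 4 when adjusted over the list alone (median −0.59, camera adjusted p = 0.0101, adjusted p = 0.544 with an estimated correlation), led by leuA (−1.49 ± 0.35), and only 1 when any single K-12 array was left out. Without K-12 replicate 2 that median was −0.91. Of 13 methionine genes 4 fell, 7 when adjusted over the list alone (median −0.69, camera adjusted p = 0.00017, adjusted p = 0.544 with an estimated correlation). All 4 lost their calls without K-12 replicate 1 and again without K-12 replicate 3, the lowest, the S-adenosylmethionine synthetase gene metK (−1.52 ± 0.82), with adjusted p = 0.0601 and 0.0537. Of 10 pyrimidine genes only pyrH fell (−0.92 ± 0.56, its call lost when any single K-12 array was left out, and −0.60 with adjusted p = 0.187 without K-12 replicate 3), and 0 when adjusted over the list alone. The pyrimidine list had a median of −0.33 (camera adjusted p = 0.013, 0.194 without K-12 replicate 3, adjusted p = 0.609 with an estimated correlation), and of 0.03 without K-12 replicate 3. After quantile normalization 10 purine, 8 methionine and 3 pyrimidine genes fell and 15 quinone and electrophile genes rose. The self-contained test fry kept 7 of the 16 list calls of K-12. It did not call iron acquisition (adjusted p = 0.06), the tricarboxylic acid cycle (0.06), acid resistance (0.063), branched-chain (0.0809), methionine (0.116), purine (0.135) or pyrimidine (0.341).

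For 2 K-12 lists the group test passed although 0 members did, over all genes or adjusted over the list alone. The 54 ribosomal protein genes had a median of −0.33 with 53 below 0 (camera adjusted p = 3.55e-06, adjusted p = 0.61 with an estimated correlation), the lowest being rpsG (−0.79 ± 0.60) and rplX (−0.70 ± 0.18). The 8 ATP synthase genes had a median of −0.42, all below 0 (camera adjusted p = 0.0119, 0.0569 without K-12 replicate 2, adjusted p = 0.544 with an estimated correlation), with atpG at −0.65 ± 0.05. Its median was −0.24 without K-12 replicate 3 and −0.64 without K-12 replicate 1. After quantile normalization 14 ribosomal protein and 4 ATP synthase genes fell. Neither list passed in fry (adjusted p = 0.38 and 0.15).

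The other K-12 lists did not pass as groups. Of 18 drug efflux genes 3 rose and 1 fell, 4 and 3 when adjusted over the list alone, with the pump genes acrB (2.81 ± 0.53), acrA (2.74 ± 0.51) and mdtG (1.90 ± 0.84) rising. The median of the efflux list was −0.07 and its mean 0.25, and the test leaned lower (camera adjusted p = 0.838). In sulphate assimilation 1 of 23 rose (cysE, named after its value was seen) and 0 when adjusted over the list alone. Arrays disagreed, as the list median was −0.98 on K-12 array 1 and 0.60 and 0.57 on arrays 2 and 3. Its median over genes was 0.38 (camera adjusted p = 0.815, and 0.000234 without K-12 replicate 1, where 6 rose), and cysH, the sulphate-reduction enzyme gene, had a ratio of 1.38 ± 4.61, or 3.89 without K-12 replicate 1 (adjusted p = 0.00877). The copper export gene copA (1.51 ± 0.60) and the copper oxidase gene cueO (1.41 ± 0.18) were the only zinc and copper genes that rose. Of 16 members, 2 rose, with 2 rising and 1 falling when adjusted over the list alone (median 0.20, camera adjusted p = 0.574). In the SOS list 3 of 19 rose, 5 when adjusted over the list alone (median 0.29, camera adjusted p = 0.0906, 0.0247 without K-12 replicate 3 and 0.0445 after quantile normalization). All 3, among them the division inhibitor gene sulA (0.91 ± 0.52), lost their calls without K-12 replicate 1 (sulA adjusted p = 0.182) and without K-12 replicate 2 (sulA adjusted p = 0.353), and sulA also without O157 replicate 1 or O157 replicate 3. Of 14 envelope stress genes only the periplasmic protease gene degP rose (1.34 ± 0.49, adjusted p = 0.0912 without K-12 replicate 1 and 0.103 without K-12 replicate 2), and 1 when adjusted over the list alone (list median 0.23, camera adjusted p = 0.423). In the aerobic respiratory chain 1 of 21 fell, the NADH dehydrogenase gene ndh (−1.86 ± 0.17), and 1 when adjusted over the list alone (median 0.00, mean −0.10, camera adjusted p = 0.229). Among anaerobic respiration and fermentation genes 3 of 23 rose and 2 fell, 3 and 2 when adjusted over the list alone, the lowest being the hydrogenase gene hybO (−1.55 ± 0.49). This list had a median of 0.23, a mean of 0.05 and a test that leaned lower (camera adjusted p = 0.714). Without K-12 replicate 2, 0 of its members rose. Of 10 arginine genes 1 fell, argG (−0.95 ± 0.48), and 1 when adjusted over the list alone (median −0.01, camera adjusted p = 0.413), and argG lost its call when any single K-12 array was left out (−0.68, adjusted p = 0.118, without K-12 replicate 3). None of 16 general stress (RpoS) genes passed, over all genes or adjusted over the list alone (median 0.27, camera adjusted p = 0.413). None of 35 flagellar and chemotaxis genes did in either way (median 0.23, camera adjusted p = 0.423). The medians of these lists depended on single arrays. Without K-12 replicate 3 they were 0.48 for flagella, 0.57 for SOS, 0.37 for zinc and copper, 0.25 for the aerobic chain and 0.18 for arginine. Leaving out K-12 replicate 2 gave 0.07 for general stress, 0.11 for anaerobic genes, −0.15 for efflux and −0.22 for sulphate assimilation, and leaving out K-12 replicate 1 gave 0.00 for flagella.

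In O157, sufA, yhhW and azoR had the highest ratios, and all 54 ribosomal protein genes fell. The transcript of sufA (b1684) rose 285-fold, to a log2 ratio of 8.15 ± 0.71 (SD, n = 3, adjusted p = 2.29e-07), yhhW to 7.64 ± 1.25 and azoR to 7.40 ± 0.25. The transcript of soxS rose to 5.84 ± 0.45, of katG to 6.69 ± 0.42 and of sodA to 4.99 ± 0.14. The transcript of fis (b3261), the nucleoid protein that activates stable RNA promoters, fell 20.5-fold, to −4.36 ± 0.84 (adjusted p = 4.03e-06), and suhB, whose product takes part in ribosomal RNA transcription, fell to −3.91 ± 0.97. The other genes among the 10 with the highest ratios were yhaK (7.35 ± 0.67), sufC (6.89 ± 0.32), the dioxygenase gene ygiD (6.88 ± 0.98), dps (6.64 ± 0.25), sufD (6.57 ± 0.43) and ybiJ (6.55 ± 0.65). The other lowest ratios were those of dusB (−3.62 ± 1.02), a transfer RNA modification gene in an operon with fis, pheP (−3.58 ± 0.81), ydeS (−3.46 ± 0.99) and cbrB (−3.45 ± 0.55). With them fell the ribosomal protein genes rpsF (−3.37 ± 1.47) and rpsR (−3.27 ± 1.18), rimO (−3.36 ± 1.11) and the xanthine permease gene xanP (−3.32 ± 0.82). The call of cbrB was lost when each spot had to pass alone. The ratio of recA was 0.15 ± 0.14 (adjusted p = 0.604). The transcript of nemA passed at 0.59 ± 0.08 (adjusted p = 0.0449), but not with arrays scaled to one spread (adjusted p = 0.0869). Of the 6 single arrays, only K-12 replicate 3 could be left out without loss of the nemA call, and without O157 replicate 1 the ratio was 0.54 (adjusted p = 0.211).

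In all, 1290 of the 3113 genes tested in O157 changed, of which 711 rose and 579 fell, and 907 differed at least 2-fold. More fell than rose with arrays centred (749 rose, 758 fell) and without O157 replicate 3 (501 and 559). The count was 783 without O157 replicate 1, and an unmoderated statistic on the 3 arrays called 5.

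Most members of the oxidative stress lists rose in O157 as well. In the SoxRS regulon 22 of 26 members rose and 1, the lipopolysaccharide kinase gene waaY (−1.64 ± 1.15, near the signal floor), fell, with 22 and 1 when adjusted over the list alone (median 1.95, camera adjusted p = 2.43e-10, adjusted p = 0.462 with an estimated correlation). The members with the highest ratios were fumC (6.23 ± 0.51), soxS and the pyruvate oxidase gene poxB (5.26 ± 0.69). In the OxyR regulon 16 of 18 rose, 16 when adjusted over the list alone (median 4.66, camera adjusted p = 2.92e-13, adjusted p = 0.462 with an estimated correlation), with ahpC at 3.90 ± 0.42. In quinone and electrophile detoxification 14 of 16 rose, 14 when adjusted over the list alone (median 2.15, camera adjusted p = 8.5e-09, adjusted p = 0.462 with an estimated correlation). The gene kefF, for a quinone oxidoreductase that activates a potassium efflux system, stood at 4.09 ± 0.90. In iron-sulphur cluster assembly 10 of 14 rose, 12 when adjusted over the list alone (median 1.29, camera adjusted p = 1.32e-06, adjusted p = 0.462 with an estimated correlation), with sufE at 5.84 ± 0.58. In iron acquisition 26 of 33 rose and 1 fell, 27 and 1 when adjusted over the list alone (median 2.52, camera adjusted p = 3.05e-10, adjusted p = 0.462 with an estimated correlation). Its highest ratios were those of entB (5.72 ± 0.30) of enterobactin synthesis and the siderophore receptor gene fhuE (5.60 ± 0.54), and the gene that fell was the ferric citrate transporter gene fecC (−1.23), named after its value was seen. In the ribonucleotide reduction and thioredoxin list 8 of 17 rose, with 8 rising and 1 falling when adjusted over the list alone (median 0.39, camera adjusted p = 0.00575, adjusted p = 0.663 with an estimated correlation). Its highest ratio was that of nrdE (6.26 ± 0.65).

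The heat shock list rose with 15 of 17 members, 15 when adjusted over the list alone, with a median of 1.08 (camera adjusted p = 5.05e-05, adjusted p = 0.462 with an estimated correlation). The small heat shock protein gene ibpA (3.44 ± 0.27) and the disaggregase gene clpB (2.37 ± 0.45) led it, and 8 members rose without O157 replicate 1. Of 16 general stress (RpoS) genes 14 rose in O157, 14 when adjusted over the list alone (median 1.64, camera adjusted p = 1.67e-05, adjusted p = 0.462 with an estimated correlation). Among them were osmY (2.62 ± 0.77) and the trehalose synthesis gene otsA (2.38 ± 0.39), and 9 rose without O157 replicate 1. In the tricarboxylic acid cycle 10 of 18 rose and 1 fell, 11 and 1 when adjusted over the list alone (median 1.02, camera adjusted p = 0.00135, adjusted p = 0.61 with an estimated correlation). Its members included acnA (4.20 ± 0.49) and the citrate synthase gene gltA (2.34 ± 0.67), and the gene that fell was the anaerobic fumarase gene fumB (−1.51), named after its value was seen. In the pentose phosphate pathway 5 of 10 rose, 6 when adjusted over the list alone (median 1.07, camera adjusted p = 0.0301, adjusted p = 0.61 with an estimated correlation), with zwf at 2.71 ± 0.34.

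All 54 ribosomal protein genes fell in O157, over all genes and adjusted over the list alone, with a median of −2.50 (camera adjusted p = 3.16e-29, adjusted p = 0.462 with an estimated correlation). Besides rpsF and rpsR the lowest were rplI (−3.26 ± 1.12) and rpsJ (−3.25 ± 0.95). All 8 ATP synthase genes fell, 8 when adjusted over the list alone (median −1.16, camera adjusted p = 0.000944, adjusted p = 0.462 with an estimated correlation), with atpA at −1.28 ± 0.38. Without O157 replicate 1, 3 of them fell, and 5 with arrays scaled. All 14 purine genes fell, 14 when adjusted over the list alone (median −1.82, camera adjusted p = 3.32e-08, adjusted p = 0.462 with an estimated correlation), among them purM (−2.81 ± 0.49) and the repressor gene purR (−2.73 ± 0.71). In pyrimidine synthesis 5 of 10 fell, 5 when adjusted over the list alone (median −0.81, camera adjusted p = 0.00623, adjusted p = 0.61 with an estimated correlation), with the dihydroorotate dehydrogenase gene pyrD at −3.03 ± 1.01. Of 12 methionine genes 5 fell and 1 rose, 5 and 1 when adjusted over the list alone (median −0.53, camera adjusted p = 0.0201, adjusted p = 0.675 with an estimated correlation). The lowest was metK (−2.53 ± 0.55), and the gene that rose was the cobalamin-dependent methionine synthase gene metH (0.73), named after its value was seen. The methionine median was −0.32 without O157 replicate 2. Of the 15 list calls of O157, fry kept all but pyrimidine (adjusted p = 0.0583) and methionine (adjusted p = 0.0623).

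The other O157 lists did not pass as groups. Of 9 acid resistance genes 5 rose and 1 fell, 6 and 1 when adjusted over the list alone (median 0.81, camera adjusted p = 0.125). The glutamate decarboxylase genes gadA (1.98 ± 0.60) and gadB (1.75 ± 0.52) rose and gadE (−1.82 ± 0.56) fell. Without O157 replicate 1, or with arrays scaled, 3 of these genes rose. Of 9 branched-chain amino acid genes 3 rose and 6 fell, 3 and 6 when adjusted over the list alone (median −0.84, camera adjusted p = 0.135), with ilvN (−1.89 ± 0.24) lowest and ilvA (1.14 ± 0.34) highest, and 3 fell without O157 replicate 2. In arginine synthesis 5 of 10 rose and 2 fell, 6 and 2 when adjusted over the list alone (median 0.77, camera adjusted p = 0.165), with argE at 2.19 ± 0.53. Of these, 3 rose without O157 replicate 1, and 0 fell without O157 replicate 2. Of 18 efflux genes 2 rose and 6 fell, 2 and 8 when adjusted over the list alone (median −0.56, camera adjusted p = 0.08, 0.0482 without O157 replicate 2), with acrB (1.60 ± 0.28) rising and emrA (−1.36 ± 0.37) falling. Without O157 replicate 1, 3 of them fell. In the aerobic chain 2 of 21 fell, 1 when adjusted over the list alone (median −0.25, camera adjusted p = 0.055, 0.0288 with arrays centred on their medians, 0.0444 after quantile normalization or without O157 replicate 1, 0.0462 without K-12 replicate 3 and 0.0338 without O157 replicate 3), with ndh at −2.85 ± 0.24. Without O157 replicate 1, 1 gene fell, and 6 with arrays centred. Of 16 zinc and copper genes 4 rose and 2 fell, 4 and 2 when adjusted over the list alone (median 0.51, camera adjusted p = 0.412). The regulator gene zntR stood at 1.79 ± 0.72 and the zinc exporter gene zntA at −1.35 ± 0.41, and 2 rose without O157 replicate 1 and 7 without O157 replicate 2. Among 35 flagellar and chemotaxis genes 4 rose and 3 fell, 4 and 3 when adjusted over the list alone (median 0.18, camera adjusted p = 0.652). The receptor gene tap stood at 2.41 ± 0.78 and the basal body gene fliF at −1.32 ± 0.19. The counts were 2 and 2 without O157 replicate 1. Among 23 anaerobic genes 3 rose and 5 fell, 1 and 5 when adjusted over the list alone, with hybO at −2.21 ± 0.57. The anaerobic median was 0.04, the mean −0.14 and the test leaned lower (camera adjusted p = 0.591). Without O157 replicate 1, 0 rose. In sulphate assimilation 2 of 23 rose and 2 fell, 0 and 0 when adjusted over the list alone (median −0.26, camera adjusted p = 0.525). The call of cysM (−1.12 ± 0.46) was lost when any single O157 array was left out, and without O157 replicate 1 (−0.86, adjusted p = 0.176) those of the other 3 were lost too. In the SOS list 2 of 19 rose and 2 fell, 2 and 2 when adjusted over the list alone (median 0.02, mean 0.06, test lower, camera adjusted p = 0.971). Its member sulA (0.96 ± 0.60) lost the call without O157 replicate 3 (adjusted p = 0.117) and, with the other 3, without O157 replicate 1 (adjusted p = 0.137). In the envelope list only degP rose (1.37 ± 0.77), and 1 gene of 14 when adjusted over the list alone (median 0.16, camera adjusted p = 0.646). Medians here too depended on single arrays. Without O157 replicate 3 they were 0.20 for zinc and copper, −0.16 for SOS, 0.05 for the envelope list, −0.48 for the aerobic chain and 0.08 for flagella. Leaving out O157 replicate 2 gave 0.21 for SOS and −0.05 for the aerobic chain, and leaving out O157 replicate 1 gave 0.11 for sulphate assimilation and 0.15 for anaerobic genes.

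**Figure D2:**
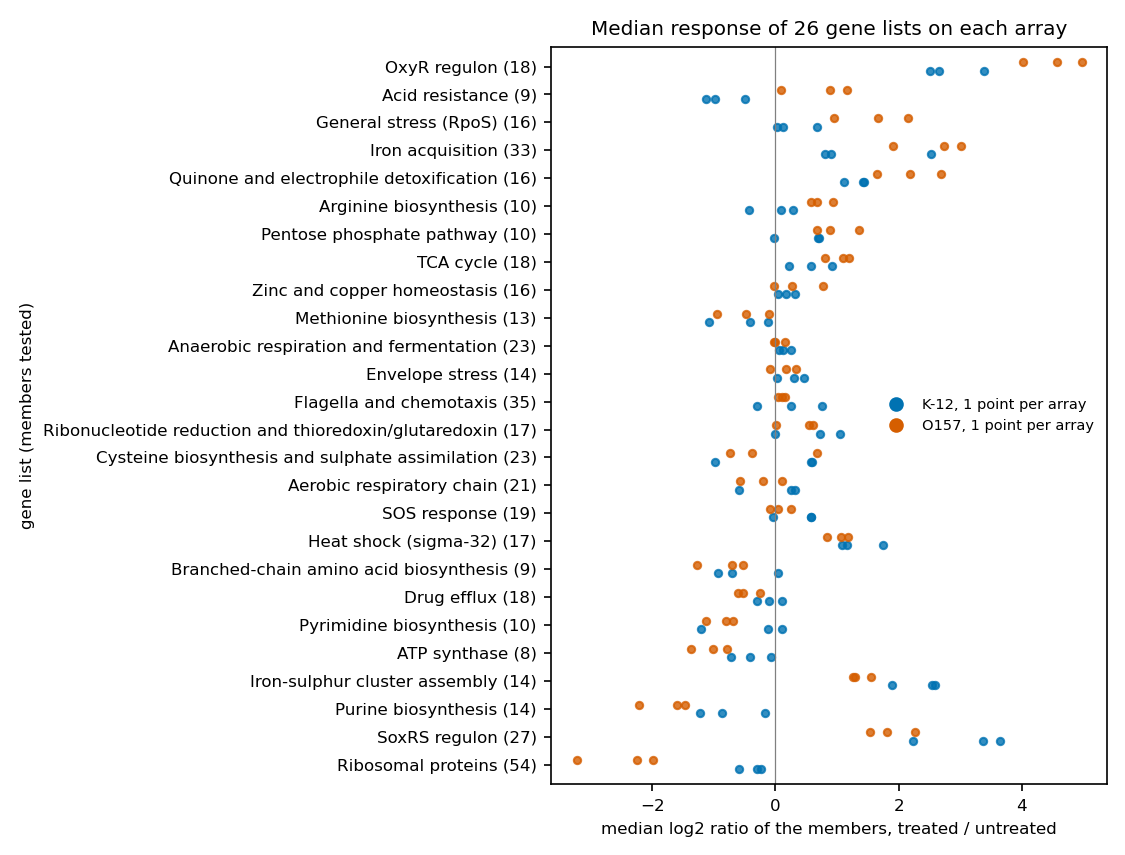
Median log2 ratio of treated over untreated RNA (horizontal axis) of the members of 26 gene lists (vertical axis, number of members tested in parentheses), 1 point per array, for 3 K-12 arrays (blue) and 3 O157 arrays (orange). Over the arrays of a strain the ribosomal protein list has a median of −0.33 in K-12 and −2.50 in O157, and the OxyR list 2.96 and 4.66.

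The responses of both strains overlapped. Of 3102 genes tested in both, 234 rose in both, among them soxS, sodA, katG, azoR and the suf genes, against 75.1 expected of independent lists (Fisher's exact test, p = 5.05e-89). A further 94 fell in both, among them ompF and pheP, against 30.7 expected (Fisher's exact test, p = 8.05e-30). The calls of both strains used 1 shared estimate of spread per gene, and the same probes and dye orientation. Genes are also not independent of each other. The expected counts and these p values take no account of this. Of the genes with the largest changes in K-12, soxS (5.79 and 5.84 in K-12 and O157), ybiJ (5.97 and 6.55), yjdM (−2.16 and −2.11) and cspC (−2.21 and −2.08) were among those with no strain difference that passed. The mean log2 ratios of the strains correlated across genes at Pearson's r = 0.677 and Spearman's rho = 0.562, where genes are not independent replicates and both strains share probes and dye orientation. Only 4 genes passed with opposite signs, all lower in K-12 and higher in O157. They were gadA (−1.08 ± 0.07 against 1.98 ± 0.60), yjbM (−2.38 against 0.95), the fimbrial recombinase gene fimB (−1.07 against 0.98) and ydcJ (−0.96 against 0.75), of which fimB and ydcJ were named after their values were seen. Of the K-12 spot values of yjbM and of ydcJ, 66.7% were missing or of dim spots. Of the O157 ones 50% of yjbM and 33.3% of ydcJ were, so yjbM was near the signal floor in both strains. The fall of gadA in K-12 kept its size but lost its call without K-12 replicate 1 (−1.06, adjusted p = 0.0904) and without K-12 replicate 2 (−1.13, adjusted p = 0.0724). A call was made in K-12 alone for 161 genes and in O157 alone for 956, which does not by itself show a strain difference. The 328 genes called in both became 545 after quantile normalization, 522 with array quality weights, 176 at an adjusted p of 0.01, and 173 without K-12 replicate 1 and 199 without K-12 replicate 2. With arrays centred, 255 rose and 165 fell in both, 60.7% higher in place of 71.3%.

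**Figure D3:**
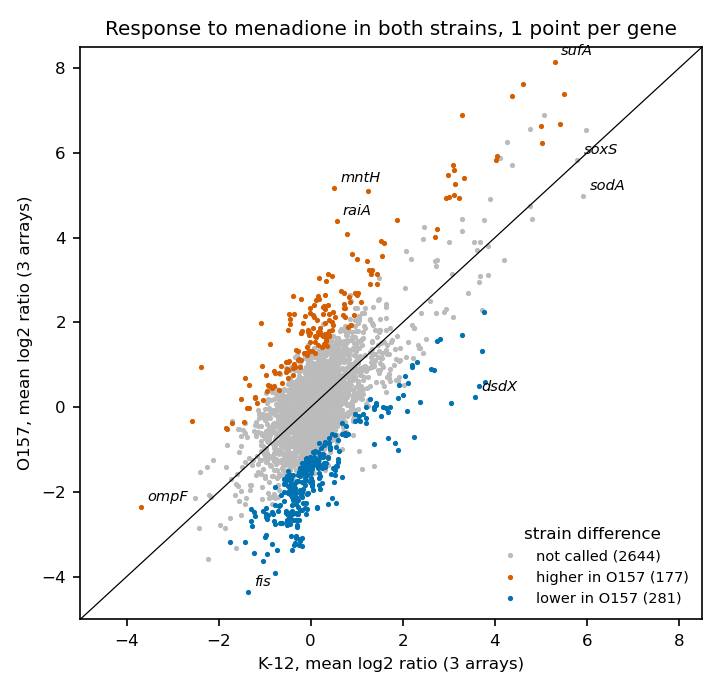
Mean log2 ratio of treated over untreated RNA in K-12 (horizontal axis, 3 arrays) against O157 (vertical axis, 3 arrays), 1 point per gene tested in both, coloured by the test of the strain difference, with equal responses on the diagonal. The 177 genes higher in O157 lie above the diagonal and the 281 lower in O157 below it, with mntH at 0.51 and 5.18 and fis at −1.36 and −4.36.

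The strains were compared by the difference of their menadione responses, in which a dye effect common to both cancels. The manganese importer gene mntH (b2392) rose 36.2-fold in O157 (log2 ratio 5.18 ± 1.03, SD, n = 3) and had a ratio of 0.51 ± 0.06 in K-12, a difference of 4.67 ± 0.46 (SE, adjusted p = 0.00109). The ribosome hibernation gene raiA (4.39 ± 0.82 against 0.56 ± 0.60) and gadA were also higher in O157. The D-serine permease and deaminase genes dsdX (b2365) and dsdA (b2366) rose in K-12 (3.56 ± 1.18 and 3.66 ± 1.02) and did not pass in O157 (0.24 ± 0.19 and 0.49 ± 0.54). Their differences were −3.32 ± 0.50 and −3.17 ± 0.49 (SE). The nitroreductase gene nfsA (b0851), a SoxRS target, rose in K-12 (3.04 ± 1.07) and had a ratio of 0.11 ± 0.61 in O157, a difference of −2.93 ± 0.51. The ribosomal protein genes rpsR (−3.08), rpsJ (−2.99) and rpsF (−2.95) were lower in O157, as were fis (−3.00) and suhB (−3.14). The remaining genes among the 10 highest differences were phoH (3.87), ygiD (3.59), yjbM (3.33), kefF (3.30), yhhW (3.02), puuE (3.01) of putrescine use and yhaK (2.99), of which yjbM was near the floor in both strains and phoH in K-12. The other lowest were ybjC (−3.19), which shares an operon with nfsA, and the galactitol dehydrogenase gene gatD (−2.94). With arrays scaled to one spread, yhhW (0.84, adjusted p = 0.111) and yhaK (0.94, adjusted p = 0.135) lost their calls, as ybjC did without K-12 replicate 2 (adjusted p = 0.0592) or O157 replicate 2 (adjusted p = 0.0526) and yjbM when each spot had to pass alone.

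The difference passed for 458 of 3102 genes, of which 177 were higher and 281 lower in O157, each at least 2-fold. The count was 707 with arrays centred, 284 with arrays scaled, 992 with array quality weights and 241 with all spots tested, and 134 without K-12 replicate 2, 148 without O157 replicate 1 and 300 without K-12 replicate 1. The share higher in O157, 38.6%, was 55.7% without O157 replicate 2 and 22.1% without K-12 replicate 3.

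All 12 list calls of the strain difference came from camera with its preset correlation, and fry called 0 (4 lists at an unadjusted p under 0.05, lowest adjusted p = 0.115). Of 54 ribosomal protein genes 52 were lower in O157, 54 when adjusted over the list alone, but 31 without K-12 replicate 2 and 34 without O157 replicate 1. Their median difference, the largest of all lists as deposited, was −2.13 (camera adjusted p = 1.89e-30, adjusted p = 0.791 with an estimated correlation), and −1.39 after quantile normalization. With arrays scaled, SoxRS (−1.87) and acid resistance (1.69) differed more than ribosomal proteins (−1.60), and after quantile normalization they did so as well (−1.47 and 1.88). In the SoxRS regulon 9 of 26 members were lower and 3 higher in O157, 12 and 3 when adjusted over the list alone. These counts were 2 and 1 without K-12 replicate 2 and 3 and 3 without O157 replicate 2, but 19 and 0 with arrays scaled and 20 and 0 after quantile normalization. The SoxRS median difference was −0.87 (camera adjusted p = 0.00351, adjusted p = 0.853 with an estimated correlation) and of −1.87 with arrays scaled. The lower members included nfsA, ybjC and the ribosomal modification gene rimK (−2.27), and soxS itself differed by 0.05 ± 0.37 (SE, adjusted p = 0.956). General stress genes were higher in O157 for 7 of 16 members, 9 when adjusted over the list alone (median 1.23, camera adjusted p = 2.18e-06, adjusted p = 0.791 with an estimated correlation), among them osmY (2.46) and otsA (2.09), and for 3 without K-12 replicate 2 or without O157 replicate 1. Acid resistance genes were higher for 5 of 9, 7 when adjusted over the list alone (median 1.48, camera adjusted p = 2e-05, adjusted p = 0.791 with an estimated correlation), led by gadA (3.06) and gadC (2.39). Purine genes were lower for 4 of 14, 6 when adjusted over the list alone (median −1.0, camera adjusted p = 0.000101, adjusted p = 0.853 with an estimated correlation), among them purR (−2.10). No purine gene was called without K-12 replicate 2, without O157 replicate 1 or with arrays scaled. The purine list passed with arrays scaled (adjusted p = 0.0419) but not after quantile normalization (median −0.46, adjusted p = 0.131). In fry the adjusted p was 0.115 for ribosomal proteins and acid resistance, 0.126 for general stress, 0.224 for purine and 0.322 for SoxRS.

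The OxyR regulon was higher in O157 for 10 of 18 members, with 13 higher and 1 lower when adjusted over the list alone, such as mntH, the ferrochelatase gene hemH (2.56) and yaaA (2.29). Its median difference was 1.51 (camera adjusted p = 1.24e-07, adjusted p = 0.791 with an estimated correlation), but 0.66 after quantile normalization (adjusted p = 0.0216) and 0.11 with arrays scaled to one spread (adjusted p = 0.329). The count of 10 was 3 without K-12 replicate 2 and 5 without O157 replicate 1, 3 higher and 1 lower with arrays scaled, and 4 and 1 after quantile normalization. Iron acquisition genes were higher for 11 of 33 and lower for 2, 18 and 3 when adjusted over the list alone (median 1.15, camera adjusted p = 2.41e-05, adjusted p = 0.853 with an estimated correlation). This list passed with arrays centred (adjusted p = 0.00032) and after quantile normalization (0.87, adjusted p = 0.0191) but not with arrays scaled (0.53, adjusted p = 0.103). There entB (2.62) lost its call (1.12, adjusted p = 0.332), as it did after quantile normalization (1.67, adjusted p = 0.0768) and without K-12 replicate 2 (1.95, adjusted p = 0.0509). Iron acquisition members called higher numbered 0 with arrays scaled, 4 after quantile normalization, 0 without K-12 replicate 2, and 20 without K-12 replicate 1, where the median was 1.87. The 2 lower members, fecC and fecE, belong to ferric citrate uptake and were named after their values were seen. Quinone and electrophile genes were higher for 5 of 16, 6 when adjusted over the list alone, with kefF and its partner kefC (2.72) called under every scaling. The median of that list was 0.31 without O157 replicate 1, 0.38 without K-12 replicate 3 and 1.19 without O157 replicate 2. With all arrays it was 0.71 (camera adjusted p = 0.00384, adjusted p = 0.853 with an estimated correlation), and it was 0.14 after quantile normalization (adjusted p = 0.462) and turned sign with arrays scaled (−0.12, adjusted p = 0.735). So did azoR (1.90 to −0.33, adjusted p = 0.664). Efflux genes were lower for 4 of 18, 5 when adjusted over the list alone (median −0.64, camera adjusted p = 0.0239, adjusted p = 0.853 with an estimated correlation), led by mdfA (−1.97), and for 0 without K-12 replicate 1, K-12 replicate 2 or O157 replicate 1. The efflux list did not pass with arrays scaled (adjusted p = 0.0728), after quantile normalization (adjusted p = 0.0701), without K-12 replicate 1 (adjusted p = 0.0535) or without O157 replicate 1 (adjusted p = 0.087). In fry the adjusted p was 0.115 for OxyR, 0.419 for iron acquisition, 0.322 for quinone and 0.224 for efflux genes.

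Tricarboxylic acid cycle genes were higher for 2 of 18, acnA (1.45) and fumC (1.22), and 1 when adjusted over the list alone (median 0.53, camera adjusted p = 0.0249, adjusted p = 0.853 with an estimated correlation). With arrays scaled the difference of fumC turned to −0.77 and the list did not pass (adjusted p = 0.471). Nor did it after quantile normalization (adjusted p = 0.391), without K-12 replicate 3 (median 0.27, adjusted p = 0.0926) or without O157 replicate 1 (adjusted p = 0.087). Both acnA and fumC lost their calls without K-12 replicate 1, K-12 replicate 2, O157 replicate 1 or O157 replicate 3. ATP synthase genes had a median difference of −0.64 with 0 of 8 called, over all genes or adjusted over the list alone (camera adjusted p = 0.0486, adjusted p = 0.853 with an estimated correlation). They did not pass with arrays scaled (adjusted p = 0.399), after quantile normalization (adjusted p = 0.562), without K-12 replicate 1 (adjusted p = 0.155), O157 replicate 1 (adjusted p = 0.143) or O157 replicate 3 (adjusted p = 0.0539). Arginine genes were higher for 3 of 10, with 6 higher and 1 lower when adjusted over the list alone (median 0.86, camera adjusted p = 0.0239, adjusted p = 0.853 with an estimated correlation), among them argE (1.49), and for 0 without K-12 replicate 2 or without O157 replicate 1. Their list did not pass without O157 replicate 1 (adjusted p = 0.114). In fry these 3 lists had adjusted p = 0.457, 0.224 and 0.254.

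The remaining lists showed no group difference that passed. Without K-12 replicate 2, 0 members were called in the iron-sulphur, ribonucleotide, pyrimidine, branched-chain, pentose phosphate, zinc and copper and envelope lists. In iron-sulphur cluster assembly 3 of 14 members were higher and 4 lower in O157, 5 and 7 when adjusted over the list alone, with sufA (2.85), sufE (1.81) and sufS (1.71) above 0 and iscX (−1.54) below. These counts were 5 and 1 without K-12 replicate 1, and 2 and 6 without K-12 replicate 3 or with arrays centred. The median of that list was −0.78, its mean 0.03 and its test lower (camera adjusted p = 0.667). With arrays scaled, the list passed as lower (median −1.58, adjusted p = 0.00177), as it did after quantile normalization (adjusted p = 0.0332), and sufA (0.53, adjusted p = 0.693), sufE (0.08, adjusted p = 0.929) and sufS (0.31, adjusted p = 0.78) lost their calls. In the ribonucleotide reduction and thioredoxin list 2 of 17 were higher, 6 when adjusted over the list alone (median 0.58, camera adjusted p = 0.0768, 0.00613 without K-12 replicate 1), such as trxC (1.32). In the heat shock list ibpA was higher (2.22) and hslR lower (−1.47), 1 and 1 of 17 when adjusted over the list alone (median −0.28, camera adjusted p = 0.909, 0.0482 after quantile normalization). The call of hslR was lost when any single array other than K-12 replicate 3 was left out. Pyrimidine genes were lower for 2 of 10, pyrD (−2.07) and pyrG (−1.44), 4 when adjusted over the list alone (median −0.68, camera adjusted p = 0.138, 0.0417 without K-12 replicate 3). The calls of pyrD and pyrG were lost with arrays scaled (limma adjusted p = 0.0904 and 0.115) and after quantile normalization (0.0698 and 0.0596). Branched-chain amino acid genes were lower for 2 of 9, ilvB (−1.37) and ilvN (−1.13), with 2 lower and 1 higher when adjusted over the list alone (median 0.09, mean −0.05, test higher, camera adjusted p = 0.955). Both ilvB and ilvN lost their calls with arrays scaled (limma adjusted p = 0.171 and 0.247) and after quantile normalization (0.123 and 0.268). In the pentose phosphate pathway 2 of 10 were higher, talA (1.67) and tktB (1.62), and 2 when adjusted over the list alone (median −0.13, mean 0.20, test higher, camera adjusted p = 0.744). With arrays scaled talA and tktB lost their calls (limma adjusted p = 0.0564 and 0.211), but not after quantile normalization (0.0117 and 0.046). Flagellar and chemotaxis genes were higher for 1 of 35, tap (2.02), and lower for 2, fliI (−1.63, near the floor in O157) and fliF (−1.24), 1 and 2 when adjusted over the list alone (median −0.05, camera adjusted p = 0.995). Both fliI and fliF lost their calls without K-12 replicate 1, K-12 replicate 2, O157 replicate 1 or O157 replicate 2. In the zinc and copper list zntR alone was higher (1.39) of 16, and in the envelope list rseC alone was lower (−1.19) of 14. Adjusted over the list alone, 0 passed in both (medians 0.06 and 0.00, camera adjusted p = 0.782 and 0.98). The envelope mean was −0.08 and its test lower. No member passed, over all genes or adjusted over the list alone, in sulphate assimilation (23 genes, median −0.50, camera adjusted p = 0.48, 0.000137 without K-12 replicate 1, where 8 were lower), methionine (12 genes, −0.11, 0.98) or SOS (19 genes, −0.42, 0.231). Nor did any in aerobic chain (21 genes, −0.34, 0.272) and anaerobic genes (23 genes, −0.19, 0.667). Medians of these remaining lists moved with single arrays. Leaving out K-12 replicate 1 gave −0.94 for sulphate assimilation, −0.05 for heat shock, −0.15 for the aerobic chain and 0.14 for flagella. Without K-12 replicate 3 they were −1.03 for pyrimidine, −0.40 for methionine and −0.22 for sulphate assimilation. Without O157 replicate 3 they were −0.42 for anaerobic genes and −0.30 for zinc and copper, and leaving out K-12 replicate 2 gave −0.26 for SOS and 0.18 for the envelope list.

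The 3 lists of O157 genes that K-12 lacks (the locus of enterocyte effacement, Shiga toxins with other virulence genes, and O-antigen with urease and tellurite genes) had 0 members among the named spots and were not analysed here.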

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

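The tests of a single array and of dim spots were chosen after the results were seen, and those of centring and scale, of splits and of exchanged channels before. These results were singled out because the response differed between strains. The difference passed for 458 genes, 177 higher and 281 lower in O157. The 10 highest were mntH (4.67), phoH (3.87), raiA (3.83), ygiD (3.59), yjbM (3.33), kefF (3.30), gadA (3.06), yhhW (3.02), puuE (3.01) and yhaK (2.99). The 10 lowest were dsdX (−3.32), ybjC (−3.19), dsdA (−3.17), suhB (−3.14), rpsR (−3.08), fis (−3.00), rpsJ (−2.99), rpsF (−2.95), gatD (−2.94) and nfsA (−2.93). Lists higher in O157 by their median difference were OxyR (1.51), acid resistance (1.48), general stress (1.23), iron acquisition (1.15), arginine (0.86), quinone and electrophile detoxification (0.71) and the tricarboxylic acid cycle (0.53). Lists lower in O157 were ribosomal proteins (−2.13), purine (−1.0), SoxRS (−0.87), drug efflux (−0.64) and ATP synthase (−0.64). These 12 calls came from camera with its preset correlation, and all were lost with an estimated correlation (adjusted p = 0.791 to 0.853) and in fry (0.115 to 0.457). The quinone median turned to −0.12 with arrays scaled.

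Ribosomal protein genes were lower in O157 than in K-12, by a median of −2.13 over 54 genes. If centring or scale were the cause, the difference would vanish under another scaling, but the value nearest 0 under 3 scalings was −1.39. If a single array were the cause, it would vanish without that array, but the value nearest 0 was −1.71. Neither the centring or scale of whole arrays nor a single array therefore accounts for most of the difference. Centring moved the median difference of all genes only from −0.04 to −0.02. These scalings use the ratios alone, so a bias that depends on spot intensity was not tested. The strain remains as a biological explanation, and strain and slide series cannot be told apart here.

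OxyR genes were higher in O157 by a median of 1.51 over 18 genes. The median difference was 1.53 with arrays centred, 0.66 after quantile normalization, where the list still passed (adjusted p = 0.0216), and 0.11 with arrays scaled to one spread, where it did not (adjusted p = 0.329), so array scale could account for most of it. The value nearest 0 without any 1 array was 1.27, which excludes a single array as the cause. Ratios were more spread in O157 than in K-12, and the data do not tell a stronger response of the strain from a wider scale of its arrays. Of the members, mntH (3.69, adjusted p = 0.00169), hemH (1.49, adjusted p = 0.0303) and yaaA (1.34, adjusted p = 0.0274) stayed called higher with arrays scaled. As deposited their differences were 4.67, 2.56 and 2.29. Scale could therefore account for part of each, but this scaling did not remove them.

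A set of 35 genes rose in K-12, did not pass in O157 and was lower in O157 in the difference, with medians of 1.63 and −0.02, dsdX, dsdA and nfsA among them. If the genes had no signal on O157 arrays, for instance because the strain lacks a matching sequence, their O157 spots would be dim. Of the 35, 3 were near the floor, against 332 of 3102 tested genes. Only genes with a value on every array were tested in the difference, so genes without O157 ratios had been left out beforehand. The low count therefore does not exclude a missing sequence. If centring were the cause, the calls would be lost with arrays centred, but 34 of 35 stayed, which argues against centring for them. Under all 3 scalings 33 stayed. Ratios on K-12 arrays had an SD of 0.83 to 1.04 against 1.12 to 1.5 on O157 arrays. Scaling to one spread therefore enlarges a rise seen in K-12 alone and could not remove it, so it does not decide about scale. The strain remains as a biological explanation, and sequence mismatch with some residual signal was not tested.

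Too few arrays were made for the splits to tell a real grouping from an arbitrary one. Of the 10 ways to split 6 arrays into 2 groups of 3, only 1, the real one, gave as many called genes (458, highest other 1), and 2 gave as many called lists (12 for the real one, highest other 13 for K-12 arrays 1 and 2 with O157 array 2). Exchanging the channels of 1 array left 0 genes called in limma's test, so 1 of 4 sign patterns reached the 512 calls of K-12 (907 at an unadjusted p under 0.05 as measured), and 1 of 4 reached the 1290 of O157.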

How the results depend on the processing

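The alternatives were fixed before the values were seen, except the natural log reading, the genes near the floor, and scaled arrays and quantile normalization in the list tests. Of the tests of single named genes under alternatives, 5306 kept their side of the threshold and their direction, 779 lost the call, 63 gained it and 3 turned. For lists the counts were 903, 93, 18 and 0. Turned were azoR in the difference with arrays scaled (−0.33) and fumC with arrays scaled (−0.77) and after quantile normalization (−0.26); the cause was not tested. Called genes in K-12 numbered 1056 after quantile normalization, 928 with weights, 273 at an adjusted p of 0.01, 250 with all columns read as natural logs, 254 to 493 with 1 array left out, and 0 with an unmoderated statistic. In O157 they numbered 5 unmoderated and 783 to 1403 with 1 array left out. In the difference they numbered 707 centred, 284 scaled, 241 with all spots, 992 with weights, 101 at 0.01, 134 to 607 with 1 array left out, and 0 with natural logs. In both strains they numbered 545 after quantile normalization, 522 with weights, 176 at 0.01, 165 with natural logs and 173 to 310 with 1 array left out. The main fit, on log2 ratios with limma's moderated statistic, called 512 genes in K-12 and 458 in the difference. In that fit, 907 and 948 genes had an unadjusted p under 0.05 in limma's test. Neither count belongs to the unmoderated or the natural log setting. Lists called numbered 43, and 0 in camera with an estimated correlation, 20 in fry (7 of 16 in K-12, 13 of 15 in O157 and 0 of 12 in the difference, where 4 lists had an unadjusted p under 0.05 in fry), and 40 to 44 with 1 array left out, of which 39 to 43 were among the 43. A stricter threshold and lost moderation explain their own falls. With 1 array left out, counts depended on which array it was. Without K-12 replicates 1, 2 and 3, calls numbered 254, 268 and 482 in K-12 and 300, 134 and 607 in the difference. Fewer arrays alone do not account for this. For these and the other changes the cause was not tested. Of the named called genes, 54 of 79 in K-12, 88 of 108 in O157 and 33 of 69 in the difference kept the call without each array in turn. With the replicate number as a block, calls numbered 451, 1185 and 466 in K-12, O157 and the difference, 293 in both, and 40 lists. Under the block the sulphate assimilation (adjusted p = 0.00581) and ribonucleotide (0.0289) lists passed in the difference, while efflux (0.0503), arginine (0.0503), tricarboxylic acid cycle (0.0542) and ATP synthase (0.119) there, and ATP synthase in K-12 (0.0684), did not. Arrays of the same number had deviations correlating at 0.153, −0.008 and −0.118, and only replicate 1 of the 3 correlated best with its own number. Not run were the median of the 2 spots, which equals their mean, and a filter on genes of each strain, which the annotation does not give. Spot intensities were not used here, so no limit from signal over background was computed.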

Other observations

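The groups below were chosen after their values were seen and carry no group test. In O157, genes that idle ribosomes and RNA polymerase rose, 5 of 5 against 1 in K-12: beside raiA, the ribosome modulation factor gene rmf (2.68 ± 0.59, SD, n = 3, against 0.72 ± 0.46 in K-12) and the sigma-70 binding gene rsd (2.12 ± 0.83 against 0.07 ± 0.24). All 5 arginine succinyltransferase genes, which serve arginine breakdown, rose in O157 (astC 3.49 ± 0.84) and 0 passed in K-12, with medians of 2.36 and 0.28. All 3 measured putrescine genes did the same (medians 2.35 and −0.11). The 6 genes of the Rsx system, which returns the SoxR sensor to its reduced state, fell in O157 (rsxC −1.94 ± 0.72) and 0 passed in K-12 (medians −1.81 and 0.23), and all 6 differed between strains. In K-12, all 5 biotin synthesis genes rose (bioC 2.09 ± 0.72) and 0 passed in O157 (medians 1.83 and 0.00). Of 5 galactitol genes, 4 rose in K-12 and 0 in O157 (medians 1.67 and −0.11), though gatA, gatC and gatZ were near the floor on O157 arrays. Nucleobase transporter genes fell in both, 4 of 5 in K-12 and 5 in O157 (codB −0.85 ± 0.53 and −3.23 ± 0.39). The 3 glycine cleavage genes (medians 1.03 and 2.14) and 3 threonine operon genes (1.32 and 2.00) rose in both.

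The fall of ribosomal protein genes with the rise of raiA and rmf led to the hypothesis, formed after these were seen, that O157 entered a slower growth programme at 10 min. The 23 aminoacyl-tRNA synthetase genes, a translation group also chosen after the values were seen, had a median strain difference of −0.68, with 20 below 0. In O157, 10 fell and 1, lysU, rose (1.25), and 0 passed in K-12. In the difference 3 passed, argS (−1.17), lysS (−1.26) and pheS (−1.52), and the median was −0.59 with arrays scaled and −0.49 after quantile normalization. The hypothesis fits these values, but they are not an independent test of it, and growth was not measured here.

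Single spots without a gene name were also called: 1084 of 5791 tested in K-12 (717 higher, 367 lower), 1848 of 6729 in O157 (1135 and 713) and 383 of 5571 in the difference (184 and 199). These were 18.7%, 27.5% and 6.9%, against 13.7%, 36.4% and 7.8% of named genes in the same fit. Ratios of small whole numbers, the mark of dim spots, made up 37.5% to 43.1% of unnamed ratios on K-12 arrays, against 10.4% to 18.4% of named ones. On O157 arrays they made up 16.3% to 27.2% against 10.0% to 18.5%. Whether dim spots account for these calls was not tested. On O157 arrays the ratio stood at the ceiling of 100000 for all 6 spot values of yieH and 4 of 6 of ydfK and insG, which were left out.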
